A study of Mus musculus with 20 samples.

How the data were processed

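RNA-seq was measured in 20 libraries of mouse MB49 bladder cancer cells, 10 from cultured cells and 10 from tumors, with 5 Y-negative and 5 Y-positive libraries of each kind, as the titles and genotypes in the labels give them. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a SMARTer mRNA kit at a sequencing company. The submitters' processing notes name cutadapt 2.3, STAR 2.7.0d, RSEM 1.3.1, FastQC 0.11.5 and MultiQC 1.8 and the build mm10 (GRCm38). The roles of these tools, the annotation release, the strand setting and the counting options are not given in the sources used here, so reads of overlapping genes on opposite strands and of near-identical copies were not separated.

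Each deposited table gives whole-number read counts per gene, per the file headers, and these counts were the values tested. Each also gives FPKM made by the authors, per the file headers, which served here only to recover the library total behind it. A further deposited column named for the library held a signal value, the read count divided by a constant for that library (within a relative tolerance of 1e-06). That normalized signal was used only as a check. In the table of MN14 this column equals that of MN13 for all 28025 genes, while the read counts of MN14 and MN13 are equal for 19.9% of genes, so the column was not used. The tables of cell lines list 14701 genes each and those of tumors list 28025 each, with 14650 in both. Reads outside the listed genes, judged from the FPKM, came to 0.104% to 0.356% in the cell lines and at most 0.003% in the tumors. Gene IDs were matched to GENCODE mouse release 21, of build GRCm38, where 28067 of 28076 were found on the same chromosome, and 25 names altered by a spreadsheet were replaced through the ID, as were the names absent from the table of MN12. No column of other samples was present (0).

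Library totals ran from 14557118 to 21180885 reads. Counts of 40 pairs of libraries of the same group were compared by chi-square, and the smallest value per degree of freedom was 7.99. Repeat preparations of one sample would exceed counting noise too, so this does not show that the libraries are independent, and each was counted as 1 replicate because the labels list it as a sample of its own. Among the Y-negative tumors, MN11, MN13 and MN14 differed by 7.99 to 16.2 per degree of freedom and MN12 and MN15 by 14.8, but pairs across these sets by 101.0 to 144.1. Counting intervals are 95% intervals, and a group with 0 reads was given a floor of 3 reads over the group.

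Counts were fitted with edgeR 4.0.16 (R 4.3.3): TMM normalization, filterByExpr (minimum count 10, minimum total 15), the quasi-likelihood F-test and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. Cell lines and tumors were fitted apart, each 5 against 5. The difference between the changes in tumors and cell lines, and tumor against cell line, came from a model of 4 group means over all 20 libraries and the genes listed in both kinds of table. Gene lists (32 lists holding 385 genes) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with an estimated inter-gene correlation, over lists with at least 3 tested members, and a list score is the mean log2 CPM of its members. The lists cover Y-linked genes and their X-linked partners, MHC class I, MHC class II, the interferon response, T cells, cytotoxic and NK cells, checkpoints and exhaustion, B cells, regulatory T cells, macrophages and monocytes, neutrophils, dendritic cells, fibroblasts and collagen, endothelial cells, skeletal muscle, adipocytes, skin keratinocytes, red blood cells, urothelial and epithelial genes, mesenchymal genes, proliferation, p53 targets, hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis, the unfolded protein and integrated stress response, chemokines and cytokines, matrix proteases, immediate early genes, mitochondrially encoded transcripts and reference genes. Chromosome shifts are medians, per library, of log2 CPM minus the mean of the gene over 10 libraries, for genes of at least 1 CPM, tested by a two-sided exact permutation test over 252 arrangements, whose smallest p is 0.00794. Overlaps were tested by Fisher's exact test and correlations across libraries by permutation with 100000 resamples.

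The fixed lists, the tests of groups, the alternatives named next and the rule for the genes named were set before the data were examined. The rule takes all tested members of the Y-linked, X-linked partner, MHC class I and checkpoint lists. Of every other list it takes up to 4 members with the smallest adjusted p. It adds the 10 largest changes in each direction among called genes with a mean of at least 5 CPM and no overlap between groups (predicted genes and pseudogenes left out), and the 5 genes with the smallest adjusted p in each direction of the difference between tumors and cell lines. Some genes the rule takes are not reported here. The alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a mean of at least 1 CPM, all 20 libraries in one model, at least a 2-fold change, leaving out each library, camera with a preset correlation of 0.01, an exact permutation test of list scores, genes of at least 10 CPM and a 10% trimmed mean for chromosomes. Length and GC content of the longest transcript per gene were fitted per library with natural splines of 4 degrees of freedom over genes of at least 1 CPM (99.9% of tested genes had values), and the fitted trends were removed as offsets in an alternative chosen after seeing the data. Other groupings of the libraries were drawn as 100 splits per result, the real one included.

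The procedures were tested on simulated data with 200 changed genes, drawn from the real means, dispersions and library sizes. In the simulated cell lines (12446 genes) 9.0% of 1.5-fold, 58.2% of 2-fold and 92.4% of 4-fold changes were recovered with 12 false calls. In the simulated tumors (14783 genes) the shares were 4.5%, 49.3% and 87.9% with 1 false call, and for the difference between tumors and cell lines (13740 genes) 3.0%, 29.9% and 69.7% with 3 false calls. In the simulated cell lines and tumors the list test recovered the 1 changed list, of 20 genes drawn without correlation between them. The chromosome test recovered the 1 shift of 0.3 added, judged at an unadjusted p under 0.05. The real test adjusts over 20 chromosomes, where 1 chromosome alone at the smallest p cannot pass. Its power for such a shift was therefore not tested. Other tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.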

Results

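RNA-seq read counts per gene were compared between MB49 libraries labelled Y chromosome negative and Y chromosome positive, in cultured cells and in tumors. MB49 is a mouse bladder cancer cell line, and the tumors were grown under the skin of male C57BL/6 mice, so host cells in them carry a Y chromosome. The 20 libraries form 4 groups of 5: Y-negative cell lines (BN2, BN3, BN6, BN9, BN10), Y-positive cell lines (MB8, MB11, MB17, MB19, MB34), Y-negative tumors (MN11 to MN15) and Y-positive tumors (MP6 to MP10). Summed over genes, the Y-negative cell line libraries held 19685275 reads (BN2), 20866142 reads (BN3), 19174744 reads (BN6), 19195174 reads (BN9) and 17963081 reads (BN10). The Y-positive cell line libraries held 16652745 reads (MB8), 19237041 reads (MB11), 17118386 reads (MB17), 14557118 reads (MB19) and 16872036 reads (MB34). The Y-negative tumor libraries held 14856008 reads (MN11), 17862451 reads (MN12), 21180885 reads (MN13), 17625417 reads (MN14) and 18598743 reads (MN15), and the Y-positive tumor libraries 18162799 reads (MP6), 16854161 reads (MP7), 18586325 reads (MP8), 17528247 reads (MP9) and 20656078 reads (MP10). The labels name the libraries but do not say which came from separate cultures, clones or animals, so p-values measure the spread between these libraries. Changes are given as log2 fold changes, Y-negative minus Y-positive, ± standard error with n = 5 per group, and levels as CPM, read counts scaled to library size, with their SD.

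The first comparison asked which genes differ between Y-negative and Y-positive cells in culture. The Y-linked histone demethylase genes Kdm5d and Uty were almost without reads in the Y-negative cultures. Kdm5d (ENSMUSG00000056673, mm10 chromosome Y, 897788 to 956786) had 0 reads in the 5 Y-negative libraries against 1885 in the Y-positive ones, at least 721-fold lower against a floor of 3 reads over the group. Uty (ENSMUSG00000068457, mm10 chromosome Y, 1096861 to 1245759) had 1 read against 1855, a ratio of 2128 with a 95% counting interval of 382 to 84114. MB34 held 1006 of these Uty reads, and without it the ratio was 1217 (218 to 48140), while without BN9, which held the 1 read, Uty was at least 569-fold lower against the same floor. Intervals and floors cover counting error only. The Y-linked genes Gm29650 and Uba1y, each below the count minimum of the test, had 0 reads in the Y-negative cultures against 173 and 138. MB34 held 106 of the Gm29650 reads (67 without it). Of Uba1y, MB8 held 64 reads, MB11 60, MB19 13, MB34 1 and MB17 0, so that MB17 was at 0 like the Y-negative cultures, and 74 reads were left without MB8 and 78 without MB11. Not all genes annotated on chromosome Y lost their reads in the Y-negative cultures. Gm47283 had 1717 reads against 1428 and the pseudogene Gm21742 105 against 141. The pseudogene Mid1-ps1 had 85 against 10, with 62 of the 85 in a single library. All of these lie between 90753057 and 90844040 on chromosome Y, far from Kdm5d and Uty. Gm47283 has a near-identical copy on X that can share its reads, and reads of copies were not separated for the pseudogenes either. Their reads therefore do not show that any part of chromosome Y was kept in the Y-negative cultures. Ddx3y and Eif2s3y were not analysed in the cell lines here.

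Away from the Y chromosome, Nes and Hes6 rose in the Y-negative cultures. Nes, which encodes the intermediate filament protein nestin of progenitor cells, stood at 19.3 ± 7.96 CPM (SD, n = 5) against 2.14 ± 0.90, a change of 3.16 ± 0.40 (adjusted p = 0.00991, edgeR's quasi-likelihood test). Hes6, a transcriptional regulator of neural and muscle differentiation, stood at 20.5 ± 3.03 CPM against 6.91 ± 2.50, a change of 1.57 ± 0.24 (adjusted p = 0.0470). With Kdm5d and Uty these were the 4 genes called among 12446 tested, 2 higher and 2 lower. At an unadjusted p under 0.05 there were 2100 genes, where 622 would be expected by chance, and 512 genes (4.11%, against 0.79% by chance) had no overlap between the groups. The count rested on the libraries and the tool: it was 66 without BN9, 10 without MB19, 9 without BN10, 7 without BN3 and 2 without MB11, 472 with DESeq2 and 13 with limma-voom. Nes lost its call without MB11 (adjusted p = 0.0535), and Hes6 lost it in 8 of 18 alternatives, within a range of 1.44 to 1.77.

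None of the 22 fixed gene lists with at least 3 tested members was called in the cell lines by camera with an estimated correlation, and 0 had an unadjusted p under 0.05. With a preset correlation 2 lists were called, and with the exact permutation test of list scores 0. In that last test a single list, even at the smallest possible p of 0.00794, cannot pass after adjustment. Of the proliferation list, 17 of 20 members had a positive change (median 0.37) and 4 passed the test adjusted over the list alone, all higher, although 0 passed over all genes. The DNA replication helicase genes Mcm7 (0.74 ± 0.15) and Mcm6 (1.03 ± 0.26) and the mitotic cyclin gene Ccnb2 (0.97 ± 0.26) had the smallest p in it. The proliferation list was called with the preset correlation (adjusted p = 0.00476), with adjusted p = 0.805 with an estimated correlation. Of the p53 target list, 11 of 12 members had a negative change (median -0.38), with Cdkn1a, a cell cycle inhibitor, at -0.42 ± 0.21 and Mdm2, the negative regulator of p53, at -0.48 ± 0.21. That list too was called with the preset correlation (adjusted p = 0.00476), with adjusted p = 0.821 with an estimated correlation, and 0 of its members passed adjusted over the list alone.

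Single members of other lists passed only adjusted over the list alone. Among these were Xbp1, a transcription factor of the unfolded protein response (-0.70 ± 0.17), the monocyte attractant gene Ccl7 (-1.90 ± 0.46), the immediate early gene Jun (-0.80 ± 0.22) and, of the reference genes, Gusb (0.80 ± 0.15). In the MHC class I and antigen processing list 0 of 15 members passed by either adjustment, and H2-K1, a class I heavy chain gene whose reads can be shared with its relatives, stood at -0.32 ± 0.26. The same held for the X-linked partners of Y genes (7 members tested), the checkpoint list (8) and the interferon response list (13), whose medians were -0.01, 0.12 and 0.21. Of the other lists tested in the cell lines, 0 members passed by either adjustment.

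Expression along chromosomes was compared because cultured tumor cells can gain or lose chromosomes. No chromosome was called between Y-negative and Y-positive cell lines by the two-sided exact permutation test of the median shift of its genes. The smallest p, 0.00794 on chromosome 15, is the smallest that 5 against 5 libraries can give (adjusted p = 0.159), and 4 of 20 chromosomes had an unadjusted p under 0.05. A trimmed mean in place of the median called 4 chromosomes. Single libraries stood apart: in MB19 the genes of chromosome 3 lay 0.43 (log2) above their mean over the 10 cell line libraries, with 87.0% of 552 genes above it. In BN2 the median shift was -0.28 on chromosome 7 and -0.22 on chromosome 6, and in BN10 -0.24 on chromosome 17 and -0.21 on chromosome 5. Nes lies on chromosome 3, but MB19 is a Y-positive library. The shift of that chromosome was -0.13 in the Y-negative against the Y-positive cultures (exact permutation p = 0.230), opposite in direction to the rise of Nes. In the tumors 0 chromosomes were called by this test (1 at an unadjusted p under 0.05, and 0 with a trimmed mean), and no library's shift exceeded 0.10.

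**Figure D1:**
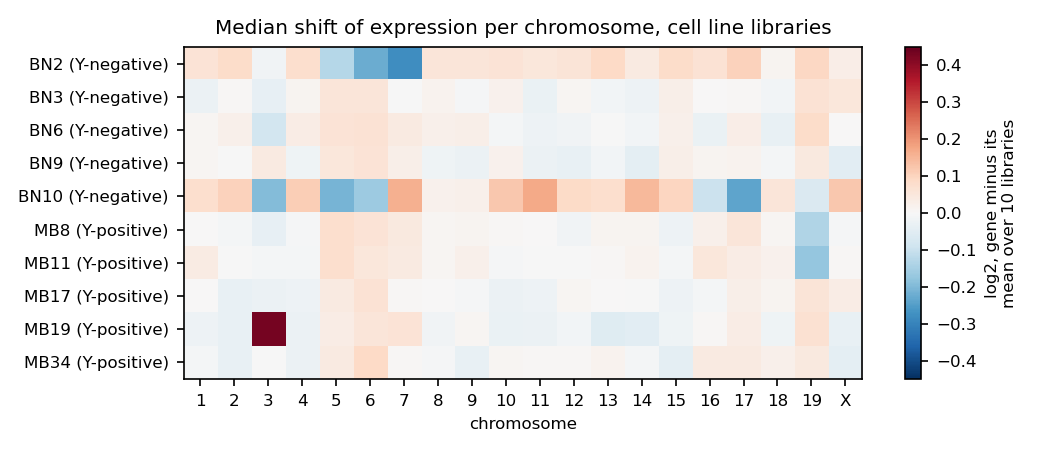
Median shift of expression (log2, colour) for each chromosome (horizontal axis) in each of the 10 cell line libraries (vertical axis), relative to the mean of each gene over the 10 libraries. Chromosome 3 in MB19 stands 0.43 above that mean and chromosome 7 in BN2 at -0.28.

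The second comparison asked which genes differ between Y-negative and Y-positive tumors grown in male mice. The 4 Y-linked genes of the list that could be tested fell in the Y-negative tumors but kept a part of their reads. Ddx3y, an RNA helicase gene (ENSMUSG00000069045, mm10 chromosome Y, 1260771 to 1286629), stood at 10.7 ± 2.80 CPM (SD, n = 5) against 76.9 ± 14.2, a change of -2.85 ± 0.20 (adjusted p = 1.63e-05, edgeR's quasi-likelihood test). Eif2s3y, a translation initiation factor gene (chromosome Y, 1010543 to 1028847), changed by -3.07 ± 0.31, Kdm5d by -2.66 ± 0.27 and Uty by -2.68 ± 0.31. Their reads stood at 12.1% to 15.6% of the Y-positive level. Gm29650, a non-coding Y-linked RNA, had 2 reads against 140, or 1.45% with a 95% counting interval of 0.174% to 5.35%. Of their X-linked partners 0 of 7 passed by either adjustment, with Kdm5c at 0.57 ± 0.19, Usp9x at 0.73 ± 0.30 and Kdm6a at 0.41 ± 0.17, but Eif2s3x at -0.22 ± 0.18 and Zfx at -0.01 ± 0.13. The score of that list stood 0.27 higher, and 0.14 higher (53.5% of the difference) after length and GC trends were removed, where Kdm5c was at 0.37, Usp9x at 0.35 and Kdm6a at 0.23. Gm47283, annotated on chromosome Y with a near-identical copy on X that can share its reads, stood at 27.5 CPM against 11.3 and was chosen after its values were seen.

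**Figure D2:**
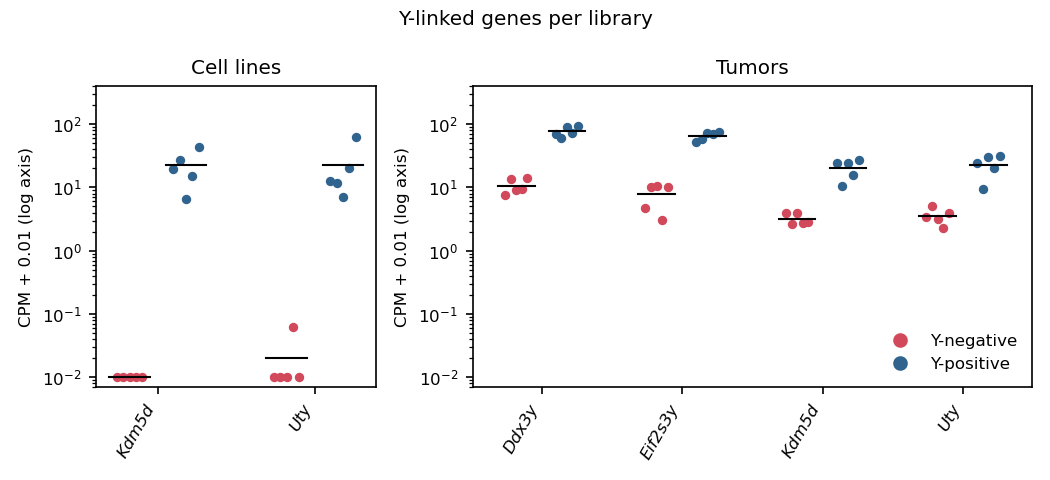
Expression (CPM + 0.01, log axis) of Y-linked genes in each cell line library (left) and tumor library (right), Y-negative in red and Y-positive in blue, with a black line at the mean of 5 libraries. Kdm5d has 0 reads in the Y-negative cultures, whereas in the Y-negative tumors the 4 genes keep 12.1% to 15.6% of the Y-positive level.

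In the tumors 362 of 14783 tested genes were called, 214 higher and 148 lower in the Y-negative group, and 868 genes (5.87%, against 0.79% by chance) had no overlap between the groups. By size, the first of the genes that rose was Anpep, which encodes the membrane peptidase CD13, at 299.9 ± 90.7 CPM against 38.1 ± 9.92 (2.98 ± 0.25, adjusted p = 8.59e-05). It was followed by the bicarbonate transporter gene Slc4a4 (1.67 ± 0.29), the matrix-associated signalling gene Nov (1.53 ± 0.13), the circadian clock gene Per3 (1.52 ± 0.20), the transcription factor gene Zbtb20 (1.5 ± 0.26), Strc (1.49 ± 0.17), Elfn2 (1.48 ± 0.23), the clock gene Per2 (1.46 ± 0.28), the acid phosphatase gene Acpp (1.42 ± 0.32) and the coronin gene Coro6 (1.40 ± 0.30). Among the genes that fell, Gldc of glycine cleavage stood at 2.21 ± 0.73 CPM against 13.1 ± 1.58 (-2.55 ± 0.24, adjusted p = 0.000156) and the basal keratin gene Krt14 at 22.3 ± 3.81 CPM against 108.4 ± 29.3 (-2.28 ± 0.20). The mast cell protease genes Cma1 (-2.47 ± 0.46) and Mcpt4 (-2.15 ± 0.39) and the granzyme gene Gzmf (-2.24 ± 0.42) fell as well, and each belongs to a gene family whose members can share reads. The others were the epithelial serpin gene Serpinb5 (-2.29 ± 0.44), Pi16 (-2.16 ± 0.38), the retinoic acid binding protein gene Crabp1 (-2.15 ± 0.34), the matrix protease gene Mmp3 (-2.14 ± 0.36) and the keratin gene Krt6a (-2.10 ± 0.36), which can share reads with its neighbour Krt6b. The count of calls was 80 without MN11, 796 without MN12, 171 without MN13, 84 without MN14, 80 without MP8, 151 without MP9, 169 without MP10 and 1331 with DESeq2. Acpp lost its call in 8 of 19 alternatives, Coro6 in 8, Serpinb5 in 4, Cma1 and Gzmf in 3 of 18 and Per2 in 3 of 19, while Anpep, Nov, Per3, Krt14, Gldc and Crabp1 kept it in all of those run.

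**Figure D3:**
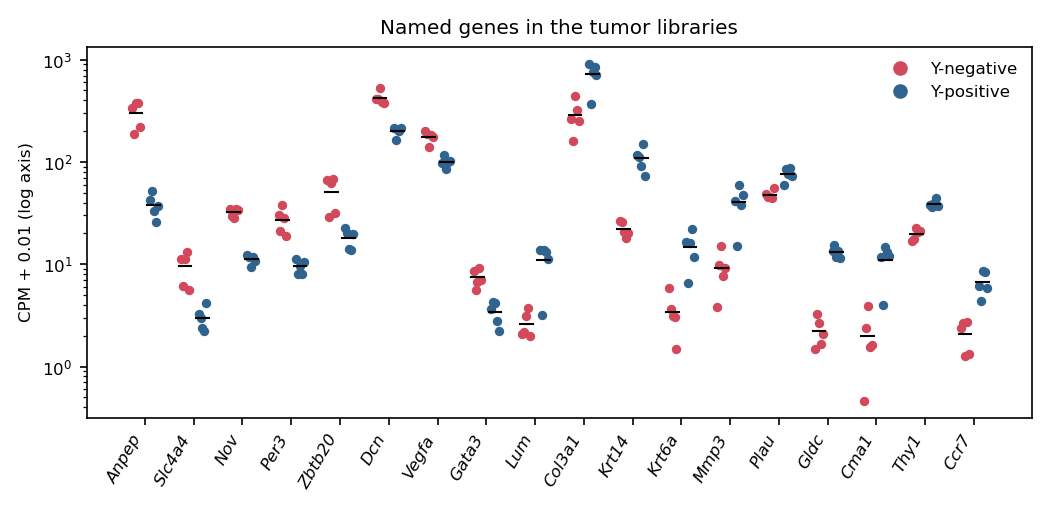
Expression (CPM + 0.01, log axis) of 18 named genes in each tumor library, Y-negative in red and Y-positive in blue, with a black line at the mean of 5 libraries. Anpep stands at a mean of 299.9 CPM in the Y-negative tumors against 38.1, and Krt14 at 22.3 against 108.4.

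Of 31 lists tested in the tumors, 0 were called by camera with an estimated correlation (2 at an unadjusted p under 0.05). With a preset correlation 11 were called, and by the exact permutation test of list scores 0. That last test gave the Y-linked, matrix protease and urothelial lists the smallest p it can, 0.00794, yet adjusted p = 0.0820. Its 0 is therefore no evidence against these lists. Leaving out MN14 gave 1 list with the estimated correlation. The Y-linked list had adjusted p = 0.0693 with an estimated correlation, with 4 of 4 members lower. In the hypoxia and glycolysis list 14 of 15 members had a positive change (median 0.40), 3 rose over all genes and 8 passed adjusted over the list alone, all higher. Vegfa, the angiogenic growth factor, stood at 0.82 ± 0.13 (adjusted p = 0.0114, edgeR), the prolyl hydroxylase gene Egln3 at 0.62 ± 0.13 and the oxidoreductase gene Ero1l at 0.67 ± 0.16, with Ndrg1 at 0.57 ± 0.14. The list was called with the preset correlation (adjusted p = 0.000148), with adjusted p = 0.509 with an estimated correlation. Egln3 lost its call in 8 and Ero1l in 11 of 19 alternatives, among them those without MN11, MN13, MN14, MP8, MP9 or MP10, with ranges of 0.55 to 0.75 and 0.58 to 0.73.

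The matrix protease and invasion list had 10 of 14 members with a negative change (median -0.48). Mmp3 and the urokinase gene Plau (-0.66 ± 0.13) fell over all genes, and adjusted over the list alone 9 members were lower and 1 higher, with the urokinase receptor gene Plaur at -0.57 ± 0.18. It was called with the preset correlation (adjusted p = 0.00783), with adjusted p = 0.152 with an estimated correlation. Of the urothelial and epithelial list, the transcription factor gene Gata3 rose (1.13 ± 0.24), whereas E-cadherin (Cdh1, -1.32 ± 0.34) and the keratin genes Krt19 (-1.63 ± 0.41) and Krt7 (-2.30 ± 0.66) did not pass over all genes. Adjusted over the list alone 5 of its 10 members were lower and 1 higher, with adjusted p = 0.509 with an estimated correlation. The fibroblast and collagen list moved in both directions. The proteoglycan gene Dcn rose (1.07 ± 0.14), while its relative Lum (-2.07 ± 0.36) and the fibrillar collagen gene Col3a1 (-1.32 ± 0.28) fell, with Col1a2 at -0.99 ± 0.27. Adjusted over the list alone 5 of its 12 members were lower and 1 higher, with adjusted p = 0.606 with an estimated correlation. In the mesenchymal list the gelatinase gene Mmp2 fell (-1.26 ± 0.30). Fibronectin (Fn1, 1.36 ± 0.33, adjusted p = 0.0507, edgeR) and the transcription factor genes Zeb2 (0.68 ± 0.18) and Snai2 (0.64 ± 0.20) did not pass over all genes. With length and GC trends removed Zeb2 was at 0.23 and Fn1 at 0.97 (adjusted p = 0.0248), and with the length slope as a covariate Zeb2 was at 0.40 and Fn1 at 0.66 (adjusted p = 0.0155). Adjusted over the list alone 3 of 12 members were higher and 1 lower, with adjusted p = 0.973 with an estimated correlation. Plau and Gata3 lost their calls in 8 of 19 alternatives each, Mmp2 in 10, Col3a1 in 6 and Lum in 3 of 18, mostly those without MN11, MN13, MN14, MP8, MP9 or MP10. Their ranges were -0.74 to -0.48, 0.96 to 1.21, -1.62 to -1.11, -1.67 to -1.11 and -2.32 to -1.79.

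In the T cell list 15 of 16 members had a negative change in the Y-negative tumors (median -0.46). Its score in log2 CPM was 1.46 in MN11, 1.88 in MN13 and 1.41 in MN14, but 2.20 in MN12 and 2.31 in MN15, against 1.78 in MP6, 2.22 in MP7 and 2.54 to 2.82 in MP8, MP9 and MP10. Across the 10 tumor libraries the score also moved with the slope of expression on transcript length (Pearson r = -0.875). Thy1, a surface glycoprotein of T cells and of fibroblasts, fell (-0.98 ± 0.13, adjusted p = 0.00240, edgeR) and was the 1 member to pass by either adjustment, whereas the receptor chain gene Trac stood at -0.59 ± 0.22 and Cd2 at -0.84 ± 0.33. The cytotoxic and NK cell list had 12 of 13 members with a negative change (median -0.74), and 0 passed by either adjustment, with perforin (Prf1) at -0.93 ± 0.33 and Gzmb at -0.76 ± 0.28. In the dendritic cell list the chemokine receptor gene Ccr7 fell (-1.68 ± 0.30), with Itgax at -0.59 ± 0.16 and Zbtb46 at -0.97 ± 0.35, and 3 of 9 members were lower adjusted over the list alone. The MHC class II list had 7 of 7 members with a negative change (median -0.62), and 0 passed by either adjustment. Its score was 6.43 in MN11 and 6.46 in MN14, while MN12, MN13 and MN15 (7.56 to 7.72) lay level with MP6, MP7 and MP9 (7.34 to 7.66) and below MP8 (8.39) and MP10 (8.06). These 4 lists were called with the preset correlation (adjusted p = 0.00328, 0.00595, 0.0205 and 0.00783), with adjusted p = 0.570, 0.570, 0.509 and 0.570 with an estimated correlation. Ccr7 lost its call without MP8, within a range of -1.82 to -1.48.

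In the MHC class I list 14 of 16 members had a negative change (median -0.20), and 0 passed by either adjustment. The list had adjusted p = 0.0585 by camera with the preset correlation. The immunoproteasome gene Psmb10 stood at -0.73 ± 0.26 and the peptide transporter gene Tap1 at -0.16 ± 0.15. The heavy chain genes H2-K1 and H2-D1, which can share reads, stood at -0.22 ± 0.16 and -0.22 ± 0.14. In the checkpoint and exhaustion list 13 of 17 members had a negative change (median -0.11), and 0 passed by either adjustment. The members included PD-L1 (Cd274, 0.12 ± 0.18), PD-L2 (Pdcd1lg2, -1.18 ± 0.40), PD-1 (Pdcd1, 0.02 ± 0.55), Lag3 (-0.22 ± 0.27) and Tox (-0.09 ± 0.47), a transcription factor of exhausted T cells. The sign of Pdcd1, Tox and Cd274 depended on the setting, and their standard errors leave differences of this size undetectable at n = 5. Over the B cell list 1 of 4 members was lower adjusted over the list alone, with the antibody joining chain gene Jchain at -2.99 ± 0.86 (-4.21 without MN12, where it was called with adjusted p = 0.0242 by edgeR, and -2.25 without MP9), and 0 of 6 members of the regulatory T cell list passed by either adjustment (median -0.53). The interferon list was level (median 0.03, 0 of 22 members past either adjustment), with Ifit3 at 0.62 ± 0.21 and Rsad2 at 0.59 ± 0.20. Among macrophage and monocyte genes, adjusted over the list alone, 4 of 16 were lower and 1 higher, with the monocyte genes Ly6c2 (-0.99 ± 0.26) and Ccr2 (-0.78 ± 0.24) and the scavenger receptor gene Cd163 (0.82 ± 0.22). In the neutrophil list 4 of 7 members were higher adjusted over the list alone, including S100a8 (1.23 ± 0.50) and S100a9 (1.19 ± 0.43). The chemokine and cytokine list had 1 of 19 members higher and 1 lower adjusted over the list alone, Cxcl1 at 1.26 ± 0.37 and Cxcl12 at -1.41 ± 0.39.

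**Figure D4:**
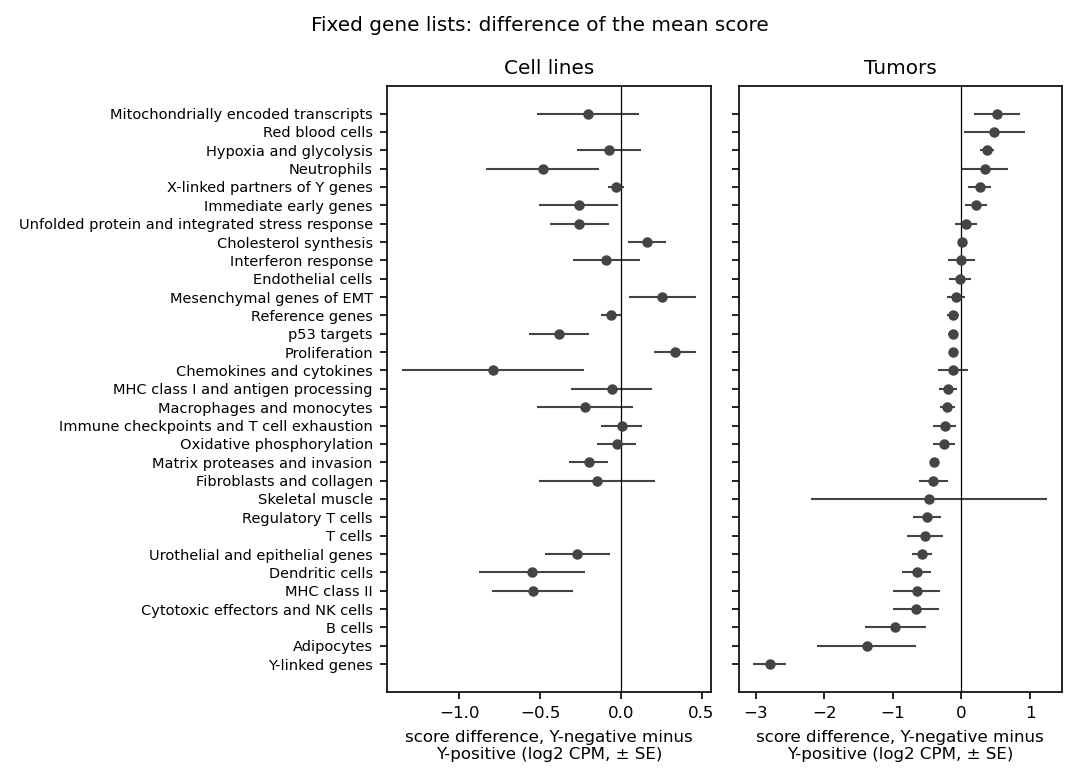
Difference of the mean list score (log2 CPM, Y-negative minus Y-positive) for each fixed list in cell lines (left) and tumors (right), with bars of ± 1 standard error from 5 libraries per group and a scale of its own for each sample type. In the tumors the hypoxia list stands at 0.37 and the T cell list at -0.53.

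Markers of other host cells were uneven among the tumors. Skeletal muscle scores ran from -1.61 log2 CPM in MP6 to 7.18 in MP9, and 0 of 10 muscle genes passed by either adjustment (median -1.62). Without MP6 and MP9, an alternative chosen after seeing the data, 42 genes were called in the tumors. Of the adipocyte genes 3 of 5 were lower adjusted over the list alone, with Cfd at -2.43 ± 0.69 (-1.61 without MP9, whose adipocyte score of 4.58 log2 CPM stood above the 1.28 to 2.83 of the other Y-positive tumors, and -3.08 without MN15, where it was called with adjusted p = 0.0403 by edgeR), and the list, called with the preset correlation (adjusted p = 0.0233), had adjusted p = 0.570 with an estimated correlation. Endothelial (median -0.11, 10 members) and red blood cell genes (median 0.68, 6 members) had 0 members past either adjustment, and the skin keratinocyte list had under 3 tested members. The lists of proliferation (20 members, median -0.15), p53 targets (12, -0.01), oxidative phosphorylation (18, -0.21), cholesterol synthesis (13, -0.08), the unfolded protein and integrated stress response (13, -0.04) and reference genes (10, -0.16) had 0 members past either adjustment. Of the mitochondrially encoded transcripts 1 of 9 was higher adjusted over the list alone (median 0.49), and of the immediate early genes 1 of 11, Fos at 1.01 ± 0.27. The proliferation, oxidative phosphorylation and mitochondrial lists were called with the preset correlation (adjusted p = 0.0205, 0.0039 and 0.0192), with adjusted p = 0.570, 0.570 and 0.604 with an estimated correlation. With length and GC trends removed, the score difference went from -0.12 to -0.08 for proliferation and from -0.26 to -0.15 for oxidative phosphorylation (58.6% kept). That of the mitochondrial list went from 0.52 to 0.79 (SDs 0.78 and 0.74 after).

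The tumor libraries also differed in how expression went with transcript length. The slope of expression on length ran from -0.23 to 0.21 log2 CPM per doubling of length, with a mean of 0.07 ± 0.16 (SD, n = 5) in the Y-negative and -0.07 ± 0.11 in the Y-positive tumors (two-sided exact permutation p = 0.127). The called genes that were higher had a median transcript length of 7050 bp and those that were lower 2497 bp, against 4002 bp over all tested genes. Across the 10 tumor libraries the slope correlated with the T cell score (Pearson r = -0.875, permutation p = 0.00147, adjusted p = 0.00294, and Spearman rho = -0.806, permutation p = 0.00673, adjusted p = 0.0135, over 4 relations computed). The correlation was -0.829 within the groups and -0.750 without MN14 and MN11, the libraries farthest from the median slope. For the oxidative phosphorylation score r was -0.994 (rho = -0.976) and within the groups -0.992, for MHC class II -0.713 (rho = -0.709, within the groups -0.604, and r = -0.328 without MN14 and MN11, on which it rests) and for the hypoxia score 0.081 (rho = 0.176, permutation p = 0.825 for r), but -0.598 within the groups. The slope and the scores come from the same expression values. A list of transcripts shorter or longer than most therefore moves with the slope by construction, which the permutation test does not address. The transcript lengths of the lists were not compared. After each library's trend on length and GC content was removed, 509 genes were called in the tumors. They held 286 of the 362 genes with the same sign.

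**Figure D5:**
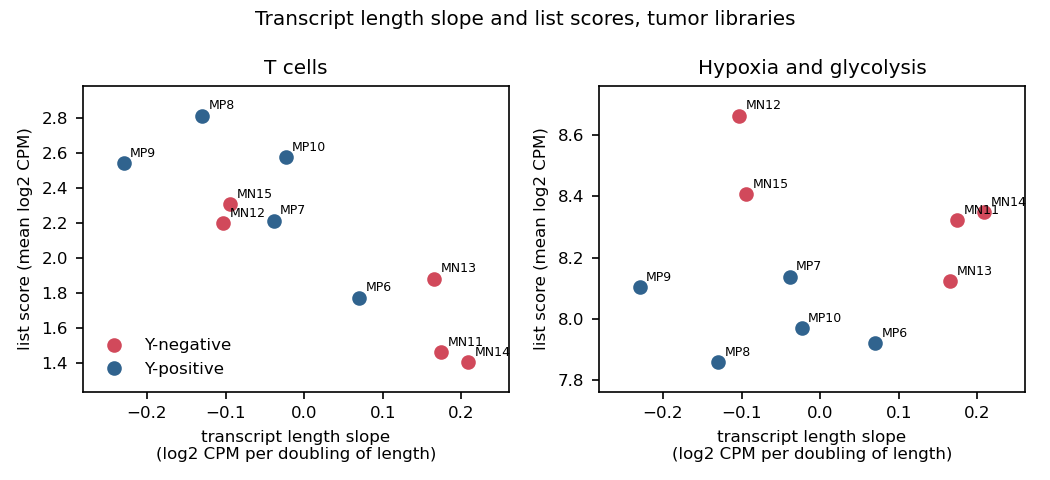
Slope of expression on transcript length (log2 CPM per doubling, horizontal axis) against the mean log2 CPM of the T cell list (left) and of the hypoxia and glycolysis list (right) in each of the 10 tumor libraries, Y-negative in red and Y-positive in blue. The T cell score falls with the slope (Pearson r = -0.875), and for the hypoxia score r is 0.081 over the 10 libraries and -0.598 within the groups.

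The third comparison asked whether the Y-negative effect differed between tumors and cell lines, and 627 of 13740 genes tested in one model differed (305 with a more positive and 322 with a more negative change in the tumors). Ltbp2, a gene of elastic fibres, was lower in the Y-negative cultures (20.2 ± 3.17 CPM against 38.0 ± 3.64, SD, n = 5). It was higher in the Y-negative tumors (23.6 ± 3.62 against 12.3 ± 2.52), a difference of 1.85 ± 0.22 between the changes (adjusted p = 0.000321, edgeR's quasi-likelihood test). Ampd3, an AMP deaminase gene (1.55 ± 0.22), and Gigyf1, a gene of translational repression (1.29 ± 0.18), went the same way. Nes (-3.04 ± 0.48) was higher in the Y-negative cultures and stood at 29.5 ± 7.62 CPM against 27.3 ± 11.7 in the tumors. The cohesin acetyltransferase gene Esco2 (-2.14 ± 0.35), the synaptic vesicle gene Syngr1 (-2.72 ± 0.45), the mitochondrial ribosome gene Noa1 (-1.52 ± 0.23) and the galectin-like gene Lgalsl (-1.35 ± 0.23) also had a more negative change in the tumors. Kdm5d and Uty differed as well, being almost without reads in the Y-negative cultures alone. These 10 genes kept their calls in 25 of 25 alternatives. The count of calls was 382 without BN6, 1031 without BN9, 310 without MB8, 306 without MB11, 329 without MB17, 171 without MN11, 1043 without MN12, 312 without MN13, 204 without MN14, 249 without MP8, 253 without MP9 and 1269 with DESeq2. None of 26 lists differed by camera with an estimated correlation (2 at an unadjusted p under 0.05, proliferation with adjusted p = 0.632 and red blood cells with adjusted p = 0.632). With the preset correlation 5 lists differed: proliferation (adjusted p = 0.00035), red blood cells (0.0107), and hypoxia and glycolysis, oxidative phosphorylation and mitochondrially encoded transcripts (0.0332 each), the last 3 with adjusted p = 0.841 with an estimated correlation.

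Cell lines and tumors shared few calls. Of 12042 genes tested in both, 0 were higher in both by edgeR, where 0.0321 would be expected of independent lists. Since only 2 genes were called higher in the cell lines, this 0 cannot tell agreement from its absence. Kdm5d and Uty were the 2 genes lower in both. Both are Y-linked, so this overlap follows from how the groups were labelled. DESeq2 shared 11 higher (19 expected of independent lists, one-sided Fisher's exact p = 0.985) and 4 lower (4.24 expected, p = 0.617) genes, and limma-voom 0 higher and 2 lower. Across 12040 genes, which are not independent replicates, the log2 changes of the 2 comparisons correlated at -0.069 (Spearman -0.074).

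Tumors and cell lines themselves differed widely, with 9559 of 13740 genes called, 4894 higher and 4665 lower in tumors, and their tables listed different gene sets. Sample type and any batch of the libraries cannot be told apart in this comparison. Only genes listed in both kinds of table entered, and 6 of 16 macrophage and monocyte genes and 4 of 10 endothelial genes were tested. Cholesterol synthesis genes stood higher in the tumors (12 of 12 members called higher, median 1.76, adjusted p = 0.0444 with an estimated correlation), the 1 list of 26 called. Of the p53 targets 11 of 12 were called lower (median -2.81, adjusted p = 0.0559 with an estimated correlation). Markers of host cells moved beside these lists: 6 of 6 MHC class II genes (median 6.86), 5 of 6 macrophage and monocyte genes (3.48), 4 of 4 endothelial genes (3.73) and 15 of 17 interferon response genes (4.14) were called higher in the tumors, each list with adjusted p = 0.0559 with an estimated correlation.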

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

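The tests of the Y-linked reads in the Y-negative tumors, the clock gene lists with their tests and the removal of length and GC trends were chosen only after the result was seen, and so was the condition that a kept difference exceed the spread between libraries, which left the tests of the T cell score and of collection time undecided.

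Libraries far from the other 4 of their group were looked for in 314 groups of values of the named genes, list scores, chromosome shifts, depth and mitochondrial share, and 18 were found where chance gives about 1 in 20 groups, or 15.7. In the cell lines these were, in CPM, Uty in BN9 (0.0522, a single read) and in MB34 (62.8, others at most 19.9), Mcm6 in MB34 (44.1), Ccnb2 in BN10 (38.1) and Jun in BN9 (494.8). In the tumors they were Dcn in MN13 (530.2), Lum in MP7 (3.16, others at least 11.2), Cdh1 in MP6 (8.95), Fos in MN11 (22.3), Jchain in MN12 (3.95), Cfd in MP9 (102.4) and Coro6 in MN15 (14.0). Among list scores in log2 CPM, matrix proteases were lowest in BN2 (6.50), immediate early genes lowest in MB19 (5.28), mitochondrial transcripts highest in MB34 (7.28) and reference genes lowest in BN10 (8.62). The shift of chromosome 3 was highest in MB19 (0.43, others -0.04 to 0.00) and that of chromosome 17 lowest in BN10 (-0.24, others 0.00 to 0.10).

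The Y-negative change differed between tumors and cell lines for 627 genes by the test of that difference (edgeR), and 2 of 100 splits of the libraries, the real one included, gave as many, with 2693 genes as the highest other. Leaving out each library in turn gave 171 (without MN11) to 1043 genes (without MN12). A split with several times the real count points to a structure of the libraries that the groups do not describe. The differences of the log2 changes, tumors minus cell lines, were 1.85 for Ltbp2, 1.55 for Ampd3, 1.29 for Gigyf1, -1.52 for Noa1, -3.04 for Nes, -2.14 for Esco2, -2.72 for Syngr1 and -1.35 for Lgalsl. For Kdm5d (9.04) and Uty (7.71) the fitted value depends on the prior count, since the Y-negative cultures held 0 and 1 reads.

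For 3 more counts under 5% of the splits gave a value as large as the real one. The splits treat the libraries as exchangeable. Where another grouping gave more calls, a chance alignment of the groups with a structure of the libraries is not excluded. In the cell lines 2 of 100 splits, the real one included, gave at least 4 genes (highest other 60, which also points to a structure of the libraries). Kdm5d and Uty among these 4 follow from how the groups were labelled, and for genes off the Y chromosome 3 of 100 gave at least the real 2. In the tumors 4 of 100 gave at least 362 (highest other 4490, then 2398 and 1013), and for tumor against cell line 1 of 100 gave 9559 (highest other 1825). The split with 4490 genes set MN11, MN13, MN14, MP6 and MP7 against the rest, which points to a structure in the tumor libraries with more called genes than the groups have. MN11, MN13, MN14 and MP6 stood together in the splits with 2398 and 1013 genes too. Among the tumors these libraries alone had a positive slope of expression on transcript length (0.17, 0.17, 0.21 and 0.07). The real groups also keep MN11, MN13 and MN14 together. Whether the length trend underlies this structure was not tested. Fixed lists called by camera were 0 in cell lines and 0 in tumors (0 and 2 at an unadjusted p under 0.05, and 2 and 11 with a preset correlation), and since any split gives at least 0, the 100 of 100 that gave as many (1 the highest other in each) say nothing about chance. The correlation of the changes between cell lines and tumors (-0.069) was reached in size by 9 of 100 splits (highest other -0.088), so chance could not be excluded.

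The tumor libraries differed in their trend with transcript length, with slopes of 0.17, 0.17 and 0.21 in MN11, MN13 and MN14 and -0.10 and -0.09 in MN12 and MN15. If these trends accounted for the tumor calls, few would remain once they were removed, but 79.0% of the called genes stayed called with the same sign, which argues against the trends as the whole cause. The hypoxia score difference kept 102% of its size (0.37 before and 0.38 after, with SDs of 0.19 and 0.13 after in the Y-negative and Y-positive tumors), which argues against them there too. For the lower T cell score 80.7% of the difference was kept (-0.53 before and -0.43 after), but the SDs after removal, 0.31 and 0.32, are nearly as large and the exact permutation p was 0.0794 before and after, so the trends and a difference in T cells cannot be told apart. What made the slopes differ was not tested, and a biological difference between Y-negative and Y-positive tumors stays open as untested.

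The Y-linked genes kept 12.1% to 15.6% of the Y-positive level in the Y-negative tumors. If cells of the injected kind with a Y chromosome gave these reads, Gm29650 would stand at a like share, but its counting interval ends at 5.35%, with 2 reads seen where the lowest share would give 16.7, so the tables argue against that source as the whole cause. Cells of the male hosts are a candidate source that stays open: Kdm5d and Uty stood at 0.0236% of the Y-positive level in the Y-negative cultures, but these were labelled by lacking the Y chromosome, so that value does not test it. The share of host cells was not measured.

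The clock genes Per1, Per2, Per3 and Tef rose in the Y-negative tumors. The list was chosen because Per2 and Per3 had been called. Without these 2 genes the other 6 clock output genes stood 0.70 higher (exact permutation p = 0.0159), against 0.90 with them. These 6 were read in the same libraries, hold the called genes Per1 and Tef, and may move together with Per2 and Per3. Leaving out Per2 and Per3 therefore does not free the p-values given here from that choice. After the removal of length and GC trends 90.8% of the difference of the whole list was kept (0.82, with SDs of 0.14 and 0.29), and 0.66 (SDs 0.10 and 0.30) without Per2 and Per3, which argues against these trends as the whole cause. Another time of day at collection would raise the output genes and lower those of the opposite phase: the output minus the opposite phase differed by 0.87 (exact permutation p = 0.0159), or 0.67 without Per2 and Per3 (p = 0.0317), but the opposite phase itself by only 0.029 (SDs 0.13 and 0.16) before and -0.089 (SDs 0.13 and 0.17) after trend removal, both within its spread. Collection time may therefore have played a part or not, and a biological difference between Y-negative and Y-positive tumors stays open as untested.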

How the results depend on the processing

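The trend offsets, the slope covariate and the sets without several libraries were chosen after seeing the data, and the other alternatives were planned. In the cell lines 4 genes were called, and 472 by DESeq2, 13 by limma-voom, 457 with all 20 libraries in one model (339 higher and 118 lower) and 19 without BN2, BN10 and MB19, each holding the 4 genes. Leaving out each library gave 2 (MB11) to 66 (BN9), with 10 without MB19, 9 without BN10 and 7 without BN3. In the tumors 362 genes were called (214 higher and 148 lower), and 1331 by DESeq2 (361 of the 362 among them), 191 changed at least 2-fold, 551 with the length slope as a covariate (273 kept) and 42 without MP6 and MP9 (41 kept). Leaving out each library gave 80 (MN11 and MP8) to 796 (MN12), with 84 without MN14, 151 without MP9, 169 without MP10 and 171 without MN13. With all 20 libraries in one model 307 were called in the tumors (231 higher and 76 lower, 168 kept). For the difference between tumors and cell lines 627 genes became 1269 by DESeq2 and 171 (MN11) to 1043 (MN12) on leaving out each library, with 1031 without BN9, 382 without BN6, 329 without MB17, 312 without MN13, 310 without MB8, 306 without MB11, 253 without MP9, 249 without MP8 and 204 without MN14. The lists called by camera rose from 0 to 2 in cell lines and to 11 in tumors with the preset correlation, and in tumors to 1 with trends removed (the Y-linked list) and to 0 to 1 on leaving out each library (1 without MN14). Calls shared in the same direction were 15 with DESeq2 against 2, and 4 chromosomes were called in the cell lines with a trimmed mean against 0. Apart from the size limit, the cause was not tested. Tumor sets with 1 library fewer gave both lower and higher counts (80 to 796 against 362), so their size alone does not account for the moves. With RLE size factors, a mean of at least 1 CPM or trends removed the gene counts stayed within 1.5 times, as did those without a filter in cell lines and tumors and with limma-voom in tumors (302) and for the difference (495).

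Signs turned for 3 genes of the tumors that were not called. Pdcd1 (0.02) was -0.13 with limma-voom, -0.0074 without a filter and -0.32 without MP6 and MP9. Leaving out each library took it from -0.42 (MN12) to 0.36 (MP8), and it was negative without MN15 (-0.18), MP6 (-0.20), MP7 (-0.17) and MP9 (-0.03) too. Tox (-0.09) was 0.15 with limma-voom and 0.059 with the slope covariate, and -0.33 (MP6) to 0.18 (MP10) on leaving out each library, positive without MN14 (0.09), MP7 (0.03) and MP8 (0.02) too. Cd274 (0.12) was -0.0021 without MP6 and MP9. The cause was not tested. Leaving out 1 library gave a call to Mcm7 (0.80), Jun (-1.06) and Gusb (0.87) in the cell lines (BN9). In the tumors it did so for Cd163 (0.95, MN12), Jchain (-4.21, MN12), Cfd (-3.08, MN15), Ccr2 (-0.95, MP7), Cxcl12 (-1.64, MP7), Itgax (-0.70, MP9), Col1a2 (-0.82, MN12, and -1.24, MN13), Zeb2 (0.76, MN12, and 0.81, MP6), Ly6c2 (-1.15, MN15 and MP6), Fn1 (1.49 to 1.52) and Krt19 (-1.83 to -1.40, both without MN12, MN15 or MP6), and Krt7, not called, was -3.02 without MN14. With length and GC trends removed, log2 changes in the tumors shrank by over 1.5 times for Zbtb20 (1.5 to 0.89, still called), Trac (-0.59 to -0.29), Zeb2 (0.23), Kdm5c (0.37), Usp9x (0.35), Kdm6a (0.23), H2-K1 (-0.11), H2-D1 (-0.12) and Lag3 (-0.15), and grew so for Tap1 (-0.26), Cd274 (0.23), Pdcd1 (0.12) and Tox (-0.22). With the slope covariate they shrank so for Zbtb20 (0.95, called), Acpp (0.91, called), Fn1 (0.66, then called), Cd2 (-0.34), Gzmb (-0.42), Psmb10 (-0.35), Jchain (-1.71), Cfd (-1.58), Ly6c2 (-0.60), Cd163 (0.53), Zeb2 (0.40), Kdm5c (0.24), Usp9x (0.14), Kdm6a (0.14), H2-K1 (-0.11), H2-D1 (-0.14) and Tap1 (-0.06), and grew for Cd274 (0.20) and Pdcd1 (0.66). Genes then called were Itgax, Col1a2, Cdh1, Fn1, S100a9, Ifit3 and Cxcl1 under both, Ly6c2, Ccr2, Cxcl12 and Fos with trends removed, and Ndrg1 and S100a8 with the covariate, while Ero1l (trends removed) and Gata3 (covariate) lost their calls. The 10 genes named for the difference between tumors and cell lines kept their calls in 25 of 25 alternatives, and in the tumors Ddx3y, Eif2s3y, Kdm5d, Uty, Anpep, Nov, Per3, Krt14, Gldc, Crabp1, Dcn and Thy1 kept theirs in each of the 18 or 19 alternatives run.

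No paired analysis was possible because the Y-negative and Y-positive libraries share no replicate number in the labels. Unrounded counts were not run, since the tables hold whole counts. At this depth and with 5 libraries per group, 49.3% of 2-fold changes were recovered in the simulated tumors, so smaller changes of single genes can be missed.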

Other observations

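The clock gene lists were chosen after Per2 and Per3 were seen among the called genes.

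In the Y-negative cultures Dbp, a transcription factor gene driven by the clock, stood at 28.1 ± 9.02 CPM (SD, n = 5) against 70.8 ± 17.8, a change of -1.33 ± 0.24 (adjusted p = 0.0672, edgeR's quasi-likelihood test). Per2 (-0.69 ± 0.18), Nr1d2 (-0.69 ± 0.18) and Tef (-0.72 ± 0.21) were lower in 5 of 5 Y-negative libraries than in any Y-positive one, but 0 of 8 clock output genes passed over all genes in the cultures, where the mean of the list stood at -1.01 (exact permutation p = 0.00794, the smallest that 5 against 5 can give). Whether the clock genes' change differed between tumors and cultures was not tested for the list. In the tumors Per1 (1.03 ± 0.23, adjusted p = 0.0383) and Tef (0.87 ± 0.20, adjusted p = 0.0465) rose beside Per2 and Per3, with Dbp at 0.76 ± 0.22 and the nuclear receptor genes Nr1d1 and Nr1d2 at 0.51 ± 0.21 and 0.27 ± 0.16. Of the opposite phase, Arntl stood at -0.27 ± 0.17, Clock at 0.11 ± 0.18 and Nfil3 at 0.21 ± 0.18 in the tumors. In the cultures the opposite phase differed by -0.24 (exact permutation p = 0.0635). The output minus the opposite phase differed there by -0.77 (exact permutation p = 0.00794).

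Single cell line libraries stood apart on further chromosomes. After the shifts given in the report, the next by size were chromosome 3 in BN10 (-0.19), chromosome 19 in MB11 (-0.17), chromosomes 11 (0.17), 6 (-0.16), 7 (0.16) and 14 (0.15) in BN10, chromosome 19 in MB8 (-0.14) and chromosome 5 in BN2 (-0.13). On chromosome 3 of MB19 the shift was 0.44 in the first part of the chromosome and 0.42 in the second. No explanation was tested for these values.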
